A study of Mus musculus with 20 samples.

How the data were processed

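Gene expression was measured by droplet-based single-cell RNA sequencing (10x Chromium 3′) in 20 mouse samples of 3 experiments, peripheral organs with 8 samples, bone marrow with 8 and recipient bone marrow with 4. Per the labels' protocols, peripheral CD45+CD11b+ cells were stained with 5 hashtag antibodies, 1 per organ, sorted, and the organs of the same animal pooled in 1 tube. The marrow fractions were sorted as negative for CD3, CD4, CD8a, CD19, Ter119 and Ly6G. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 against mm10. Per the file headers, the version was 3.1.0 for the peripheral and marrow matrices and 5.0.1 for the recipient matrix. The deposited values are counts of UMIs per gene and cell barcode in 3 matrices, integers throughout, that pool all libraries of an experiment, with a barcode suffix for each library. The peripheral matrix lists 31053 genes and 4 antibody features named B0301 to B0304, 1 fewer than the antibodies in the protocols. The recipient matrix lists 32285 genes and an EGFP sequence. No file or label ties a suffix to a sample or an antibody code to an organ, so the planned comparisons of stroke with control and of organs by name were not run. The planned tests of class shares between conditions were not run for the same reason.

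Cells were kept with at least 500 UMIs, 200 genes and at most 10% mitochondrial UMIs. Hashtags were called per library and antibody with a fitted cutoff, and 2122 cells with more than 1 hashtag were removed. Doublets were called with Scrublet in scanpy 1.11.5 per library, which removed 847 peripheral, 575 marrow and 1391 recipient cells. In peripheral library 7 its own threshold called 3 cells, so the median threshold of the other libraries was used there. Of 42013, 30133 and 45540 barcodes, 36896, 28250 and 40795 cells were kept. Libraries held 22.9e6 to 47.9e6 UMIs in the periphery, 16.0e6 to 58.9e6 in marrow and 139e6 to 175e6 in recipients. Median UMIs per cell ranged from 4365 to 5399.5, from 6916.5 to 10269.5 and from 5172 to 12269. Each experiment was clustered by itself on 2000 variable genes, leaving out all genes of the fixed lists, with 30 principal components, 30 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). A cluster took the name of the best of 24 marker sets with at least 3 raised members, or none where 2 lineages were raised or its leading genes belonged to another lineage. Of 36, 33 and 30 clusters, 26, 31 and 24 were named, and names are written as monocyte-like and so on. EGFP stayed out of totals and clustering.

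UMIs were summed per library and class into pseudobulks of at least 20 cells, in at least 3 libraries per comparison. Marrow comparisons set monocyte-like cells, classical and nonclassical together, against granulocyte-monocyte-progenitor-like cells of the same library. Hashtag comparisons set each of B0302, B0303 and B0304 against the mean of the other 2 in the same class and library. They were added when the matrix showed hashtags without organ names, before any expression value by hashtag was seen. B0301 was left out of the tests because it marked fewer than 20 classical-monocyte-like cells in each of 8 libraries and fewer than 20 neutrophil-like cells in 5 of them. Each test was an edgeR 4.0.16 quasi-likelihood fit in R 4.3.3 with TMM scaling, filterByExpr, library as a block and Benjamini-Hochberg adjustment at 0.05. Pseudobulks numbered 16, 8, 24 and 24, with 47 to 1333, 379 to 3732, 92 to 457 and 26 to 432 cells and 7, 3, 14 and 14 residual degrees of freedom, for native marrow, recipient marrow, classical-monocyte-like and neutrophil-like cells. Both arms of a pair come from the same library, which per the labels' protocols is 1 animal in the periphery. Deviations of the same library from the arm means correlated with medians of 0.314, 0.399, 0.258 and 0.207 and minima of 0.147, 0.240, 0.165 and −0.134. CPM values beside tests are scaled by TMM factors, and levels outside tests are plain CPM. The difference of the contrast between recipient and native marrow was tested as an interaction term in 1 fit over both experiments, added after the files were seen. Levels of the 2 experiments were set side by side without a test.

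For the marrow contrast only genes of 12 fixed lists, 239 genes in all, are reported, since the classes were defined from the other genes. Lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the lists. Beside them, 9 lists of RNA from other cells or tissues were tested where at least 3 members were measured. In each planned or hashtag comparison the text draws its genes from a rule written before the data were examined. It takes the 10 largest rises and falls past the threshold with 1 sign in every library and at least 50 CPM in 1 arm, up to 4 members of each fixed list with the largest change, and always Il1b, Il1r1, Ccr2 and Cx3cr1. It leaves out predicted, mitochondrial and ribosomal protein genes and genes of the other-cell lists. Genes named in the interaction, in the side-by-side levels and in the sex check were chosen after their values were seen.

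The fits were tested on simulated data of the same depth and of the average spread at each expression level. Genes were drawn independently, few of them were changed, and no library had a state of its own. The rates may therefore not carry over to the real fits. At a true 1.5-fold change 91.9% of genes were recovered in native marrow, 25.3% in recipient marrow, 84.8% in classical-monocyte-like and 70.4% in neutrophil-like cells, and at 2-fold 100, 77.1, 100 and 96.9%. False calls made up 3.70, 2.75, 6.54 and 4.76% of calls. Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, a floor of 50 CPM, at least 50 cells, doublets kept, at least 1000 UMIs per cell, no library block, each library left out, a hashtag share of at least 80%, other-cell genes removed, Leiden resolution 0.5, marker genes left out of the lists, and equal cells of equal depth. For equal depth, cells were thinned to 2000 UMIs in marrow, with 46 cells per native and 379 per recipient pseudobulk, and to 1000 UMIs by hashtag, with 92 monocyte-like and 25 neutrophil-like cells. Leaving out clusters with over 90% of cells from 1 library was added later, as were the interaction per gene and list with each library left out and the cluster shares within libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9 were used.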

Results

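Immune cells of C57BL6/J mice were profiled by single-cell RNA sequencing in 3 experiments covering 20 samples. In the peripheral experiment, CD45+CD11b+ cells were sorted from heart, lung, liver, spleen and blood of 4 control and 4 stroke animals. Per the labels, the organs of 1 animal carried their own hashtag antibodies and were pooled in 1 tube. The sort ratio was 1 for heart and 4 for the other organs, so shares of cells in a tube depend on this mix. In the marrow experiment, cells negative for CD3, CD4, CD8a, CD19, Ter119 and Ly6G came from 4 control and 4 stroke animals. In the recipient experiment the same fraction came from naive recipients of marrow, 2 with control donors and 2 with stroke donors. The cells stand in 3 pooled matrices of UMI counts with 8, 8 and 4 libraries, and no deposited file ties a library to an animal or a condition. Stroke and control were therefore not compared, and libraries are named by number. The 4 hashtags in the peripheral matrix carry the codes B0301 to B0304 without organ names, so no organ was compared by name. What the files do allow is a description of the classes, of monocyte-like against progenitor-like cells within each marrow library, of the 2 marrow experiments, and of the hashtags within each peripheral library.

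After filtering, 36896 peripheral, 28250 marrow and 40795 recipient cells remained. Peripheral libraries were led by NK-cell-like cells, with a median of 34.2% of cells (range 30.0 to 51.2%). Classical-monocyte-like cells made up 17.3% (10.2 to 22.5%), neutrophil-like cells 11.8% (6.43 to 15.3%) and nonclassical-monocyte-like cells 7.19% (4.32 to 10.7%). Cardiac-resident-macrophage-like cells, named after markers such as Lyve1, Folr2 and Timd4, made up 1.42% (0.707 to 2.72%). The name follows the marker set and does not place these cells in the heart. In the marrow, classical-monocyte-like cells were the largest class at 17.9% (14.1 to 22.2%), and granulocyte-monocyte-progenitor-like cells made up 5.42% (3.59 to 7.78%). T-cell-like and B-cell-like cells still held 12.2% and 10.8%, although the fraction was selected for lacking CD3, CD4, CD8a and CD19 on the surface. In recipients, B-cell-like cells spread from 8.92 to 51.3% of a library, classical-monocyte-like cells from 16.9 to 32.7%, and progenitor-like cells from 3.82 to 8.62%. Clusters without a name held 3.43 to 36.2% of a recipient library, mostly cycling cells.

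**Figure D1:**
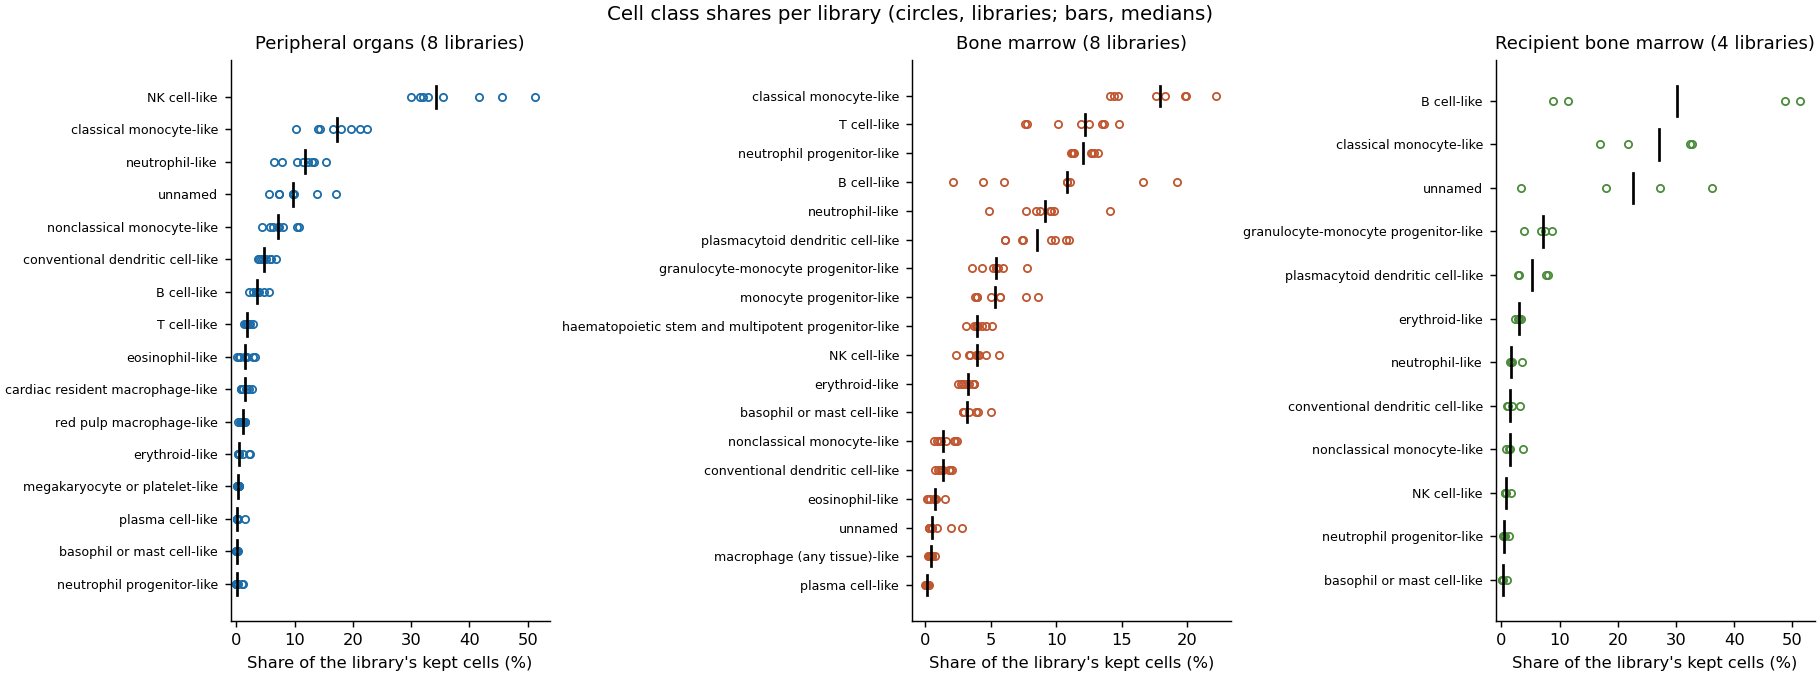
Share of each cell class in every library of the 3 experiments. Median shares of classical-monocyte-like cells were 17.3% in peripheral organs, 17.9% in marrow and 27.1% in recipient marrow.

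Levels of list genes were read in monocyte-, neutrophil-, progenitor-, resident-macrophage-, dendritic-, NK- and B-cell-like classes. T-cell-, basophil-, eosinophil-, plasma-cell-, erythroid- and megakaryocyte-like classes and unnamed clusters were left out. Among those read, Il1b (ENSMUSG00000027398) was highest in neutrophil-like cells in the periphery, and it was scarce in the marrow. Its median over libraries was 8267 CPM in peripheral neutrophil-like cells (5939 to 9888), 285 in nonclassical-monocyte-like cells (222 to 446) and 115 in classical-monocyte-like cells (73.1 to 135). Cardiac-resident-macrophage-like cells carried 172 CPM (58.6 to 321). In the marrow the same gene reached 82.8 CPM in nonclassical-monocyte-like cells (57.2 to 311), 4.29 in classical ones and 0.564 in neutrophil-like cells, whose fraction had been depleted of Ly6G. In recipients it reached 17.2 CPM in nonclassical-monocyte-like cells (7.59 to 32.5) and 0.444 in classical ones. Among the marrow classes read, Il1r1 (ENSMUSG00000026072), the receptor that binds IL-1, was highest in stem-and-multipotent-progenitor-like cells at 25.3 CPM (12.2 to 29.4). It stood at 0.874 CPM in marrow granulocyte-monocyte-progenitor-like cells and at 0.0589 in classical-monocyte-like cells. Ccr2 (ENSMUSG00000049103), the receptor monocytes use to leave the marrow, held medians of 1752, 1768 and 1319 CPM in classical-monocyte-like cells of periphery, marrow and recipients. Cx3cr1 (ENSMUSG00000052336) in nonclassical-monocyte-like cells stood at 925, 1255 and 422 CPM.

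**Figure D2:**
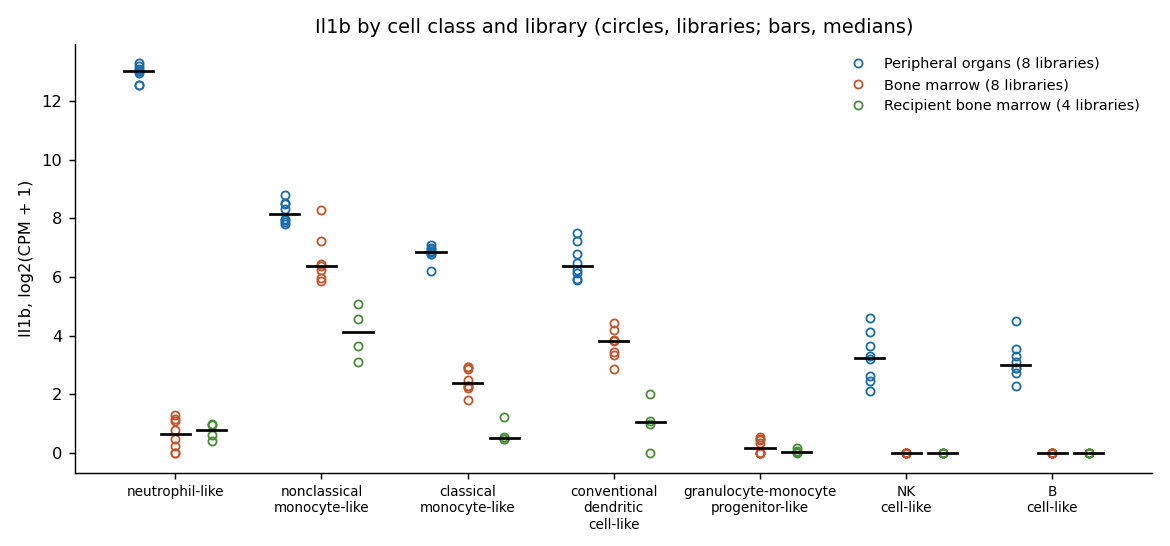
Il1b per class and library in the 3 experiments. Medians in classical-monocyte-like cells were 115 CPM in peripheral organs, 4.29 in marrow and 0.444 in recipient marrow.

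Within each of the 8 marrow libraries, monocyte-like cells were compared with granulocyte-monocyte-progenitor-like cells. The monocyte-like cells held more Il1b and Il18, whose products need inflammasome cleavage, and more of the sensor Nlrp3. They also carried the chemokine Ccl6, the interferon-stimulated genes Ifit3 and Rsad2, the antigen-presentation genes Cd74 and H2-Aa, and the lipid carrier Apoe. They held less of the replication genes Rrm2 and Mcm6 and of the maintenance methyltransferase Dnmt1. Of 202 measured genes of the 12 fixed lists, 138 were higher and 49 lower by the edgeR quasi-likelihood test, and adjusted over the list alone the counts stayed at 138 and 49. Over all 10139 genes of the fit, 4170 were higher and 4154 lower, so being called does not by itself set a list gene apart. The clusters were built without these genes, but Ccr2, Vcan, Sell, Nr4a1 and Itgal also served to name the 2 monocyte classes. Their differences are not independent of the naming. The other list genes can vary together with the genes used for clustering, so their differences are not fully independent of the classes either.

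All 24 measured interferon-stimulated genes were higher, 24 adjusted over the list alone, with a median log2 fold change of 3.21 (camera adjusted p = 2.4e-08). With an estimated correlation the adjusted p = 0.16. Ifit3 rose by 7.57 ± 0.21 log2 (median 0.0589 to 49.0 CPM, edgeR adjusted p = 4.5e-19), Rsad2 by 6.24 ± 0.19 (0.485 to 41.3) and Oasl2 by 4.86 ± 0.12 (1.597 to 66.1), each in 8 of 8 libraries. Of 20 cytokine and NF-kB genes, 18 were higher, 0 lower and 2 not called, and 18 were higher adjusted over the list alone (camera adjusted p = 3.4e-05; adjusted p = 0.16 with an estimated correlation). Ccl6 rose by 4.60 ± 0.15 log2 (35.7 to 1010 CPM), Cxcl10 by 3.88 ± 0.41 (2.73 to 52.2), Ccl2 by 2.96 ± 0.23 (0.585 to 6.66) and Relb by 2.92 ± 0.14. Of 15 genes of the IL-1 pathway, 11 were higher and 4 lower, 11 and 4 adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.16 with an estimated correlation). Il1b rose by 5.41 ± 0.34 log2 (0.138 to 7.45 CPM, edgeR adjusted p = 1.5e-12), Il18 by 4.14 ± 0.16 (1.43 to 23.1), Il1rn by 2.52 ± 0.24 (1.08 to 5.85) and Nlrp3 by 2.47 ± 0.10 (6.25 to 35.5). The 4 lower genes, named here after their values were seen, were Il18rap, the decoy receptor Il1r2, Irak1 and Il1rap.

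Chemokine receptors and adhesion genes were 12 higher and 3 lower of 15, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0048; adjusted p = 0.18 with an estimated correlation). Cx3cr1 rose by 3.45 ± 0.12 log2 (37.8 to 427 CPM), Ccr2 by 2.74 ± 0.11 (268 to 1755) and Ccr1 by 2.19 ± 0.14 (13.5 to 59.9). Of 14 scavenging and lipid genes, 13 were higher, 0 lower and 1 not called, 13 adjusted over the list alone (camera adjusted p = 0.00018; adjusted p = 0.16 with an estimated correlation), led by Apoe at 5.79 ± 0.13 log2 (17.6 to 1038 CPM), with Msr1 at 3.47 ± 0.21 (7.93 to 85.8). Of 12 MHC class II genes, 11 were higher and 1 lower, 11 and 1 adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.16 with an estimated correlation). Cd74 rose by 5.69 ± 0.52 log2 (8.48 to 779 CPM) and H2-Aa by 5.31 ± 0.51 (2.28 to 280). Of 15 matrix genes, 12 were higher, 1 lower and 2 not called, 12 and 1 adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.16 with an estimated correlation). Vcan rose by 4.23 ± 0.23 log2 (5.17 to 115 CPM) and Mmp8 by 3.59 ± 0.19 (14.9 to 155), while Vegfa, at a median of 13.5 CPM in the progenitor-like cells, had a median of 0 in the monocyte-like ones.

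Of 21 immediate-early genes, 13 were higher, 5 lower and 3 not called, 13 and 5 adjusted over the list alone (camera adjusted p = 0.049; adjusted p = 0.30 with an estimated correlation), with Atf3 at 5.94 ± 0.19 log2 and Fosb at −3.03 ± 0.17. Of 17 cell-cycle genes, 4 were higher, 10 lower and 3 not called, 4 and 10 adjusted over the list alone (camera adjusted p = 0.049; adjusted p = 0.41 with an estimated correlation). Rrm2 fell by 3.96 ± 0.09 log2 (193 to 11.7 CPM) and Mcm6 by 3.45 ± 0.07 (238 to 21.2). Glycolysis genes split into 7 higher, 11 lower and 1 not called of 19, 7 and 11 adjusted over the list alone. Pfkfb4 rose by 1.70 ± 0.07 log2 and Ldha fell by 1.17 ± 0.05 (382 to 176 CPM). Chromatin modifiers split into 8 higher, 8 lower and 1 not called of 17, 8 and 8 adjusted over the list alone, with Dnmt1 down by 2.13 ± 0.05 log2 (236 to 52.3 CPM), Ezh2 down by 1.67 ± 0.07 (146 to 49.8) and Ep300 up by 1.16 ± 0.05 (71.3 to 165). Cholesterol-synthesis genes were 6 higher, 6 lower and 2 not called of 14, 6 and 6 adjusted over the list alone, with Ldlr at 1.85 ± 0.07 log2 and Fdps at −1.23 ± 0.06. Among lists of RNA from other cells, neutrophil RNA, the genes that mature neutrophils carry, stood lower in the monocyte-like cells with a median log2 of −3.71 over 8 genes (camera adjusted p = 0.016; adjusted p = 0.50 with an estimated correlation). No other-cell list besides passed camera here.

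In the 4 recipient libraries the same contrast was drawn between monocyte-like and progenitor-like cells. Here too Il1b, Il18, Ccl6, the integrin Itgam and the interferon-stimulated genes Ifit3 and Ifi27l2a were higher in monocyte-like cells. The decoy receptor Il1r2, named here after its value was seen, was higher as well, unlike in native marrow, and Il1r1 was lower. The glycolysis regulator Pfkfb4 and the lactate exporter Slc16a3 rose as well, and Rrm2 and Mcm6 fell. Of 215 measured list genes, 132 were higher and 44 lower by edgeR, and 133 and 45 adjusted over the list alone. Over all 12619 genes of the fit, 4513 were higher and 4463 lower. Without library 2 the lower count was 25 and without library 4 it was 24.

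Of 24 interferon-stimulated genes, 22 were higher, 0 lower and 2 not called, 23 higher adjusted over the list alone (camera adjusted p = 1.6e-06; adjusted p = 0.55 with an estimated correlation). Ifit3 rose by 6.67 ± 0.36 log2 (0.290 to 43.2 CPM, edgeR adjusted p = 0.00053) and Ifi27l2a by 4.63 ± 0.39 (109 to 3032). Over the libraries, Ifit3 in monocyte-like cells ranged from 1.47 to 45.8 CPM. In classical-monocyte-like cells of library 3, Oasl2, Isg15, Irf7 and Stat1 stood at least 2-fold below every other recipient library. Of 22 cytokine and NF-kB genes, 19 were higher, 0 lower and 3 not called, 19 adjusted over the list alone (camera adjusted p = 6.0e-05; adjusted p = 0.55 with an estimated correlation). Ccl6 rose by 5.22 ± 0.39 log2 (16.3 to 793 CPM) and Ccl2 by 3.29 ± 0.17 (0.770 to 7.66). Of 16 IL-1 pathway genes, 12 were higher, 2 lower and 2 not called, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0044; adjusted p = 0.55 with an estimated correlation). Il1b rose by 5.17 ± 0.68 log2 (0.0346 to 1.08 CPM, edgeR adjusted p = 0.0018), Il1rn by 3.84 ± 0.22 (0.399 to 6.22) and Il18 by 3.60 ± 0.35 (1.42 to 20.7). Il1r1 fell by 3.15 ± 0.26 log2 (1.95 to 0.193 CPM), in 4 of 4 libraries. Il1b is close to absent from the progenitor-like cells of both experiments, so the size of its rise hangs on a handful of UMIs. The monocyte-like arm also pools classical and nonclassical cells, and Il1b was higher in the nonclassical ones in both experiments. Of 16 chemokine receptors and adhesion genes, 13 were higher, 0 lower and 3 not called, 13 adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.55 with an estimated correlation). Ccr1 rose by 4.02 ± 0.25 log2 (5.79 to 110 CPM), Itgam by 3.91 ± 0.30 (16.3 to 260), Ccr2 by 2.41 ± 0.22 (256 to 1398) and Cx3cr1 by 1.70 ± 0.42 (37.8 to 151, edgeR adjusted p = 0.017).

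Of 18 matrix genes, 13 were higher, 2 lower and 3 not called, 13 and 2 adjusted over the list alone (camera adjusted p = 0.0050; adjusted p = 0.55 with an estimated correlation). Vcan rose by 6.10 ± 0.53 log2 and Fn1 by 5.11 ± 0.39 (39.6 to 1643 CPM). Of 16 scavenging genes, 12 were higher, 3 lower and 1 not called, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.55 with an estimated correlation), led by Msr1 at 5.87 ± 0.23 log2 (1.02 to 62.2 CPM) and Apoe at 4.42 ± 0.37. Of 12 MHC class II genes, 10 were higher, 1 lower and 1 not called, 10 and 1 adjusted over the list alone (camera adjusted p = 0.0096; adjusted p = 0.55 with an estimated correlation), with Cd40 at 3.88 ± 0.53 log2 and Cd74 at 3.82 ± 0.54 (19.9 to 295 CPM). Of 17 cell-cycle genes, 1 was higher, 9 lower and 7 not called, 1 and 8 adjusted over the list alone (camera adjusted p = 0.049; adjusted p = 0.70 with an estimated correlation). Rrm2 fell by 3.02 ± 0.82 log2 (128 to 10.2 CPM), and its monocyte-like range reached from 6.29 to 168 CPM. Top2a reached 787 CPM in monocyte-like cells and was higher there than in progenitor-like cells in 1 of 4 libraries. In classical-monocyte-like cells of library 3, 16 of the 17 list genes stood at least 2-fold above the other libraries. Cycling clusters that took the monocyte name came almost wholly from that library, and other cycling clusters took no name. The remaining lists did not pass camera. Immediate-early genes were 13 higher, 7 lower and 5 not called of 25 (13 and 8 adjusted over the list alone), with Atf3 at 5.55 ± 0.38 log2. Glycolysis genes were 8 higher, 8 lower and 3 not called of 19 (8 and 8), with Pfkfb4 at 3.03 ± 0.20 log2 (3.85 to 34.8 CPM) and Slc16a3 at 2.42 ± 0.16 (6.35 to 34.1). Chromatin modifiers were 8 higher, 6 lower and 3 not called of 17 (8 and 6), with Ezh2 at −2.03 ± 0.50 log2 and Kdm6b at 1.56 ± 0.14. Cholesterol genes were 2 higher, 6 lower and 6 not called of 14 (2 and 6), with Fdps at −1.49 ± 0.16 log2 and Ldlr at 1.65 ± 0.19.

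Other-cell lists moved in recipients as well. Neutrophil RNA was higher in monocyte-like cells (median log2 0.82 over 7 genes). Lung-epithelium RNA, which includes the lysozyme gene Lyz1, was higher too (5.01 over 5 genes). Cardiomyocyte RNA, which includes Cox6a2 of plasmacytoid dendritic cells, was lower (−1.73 over 6 genes). Each had a camera adjusted p = 0.042, and for each the adjusted p = 0.45 with an estimated correlation.

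**Figure D3:**
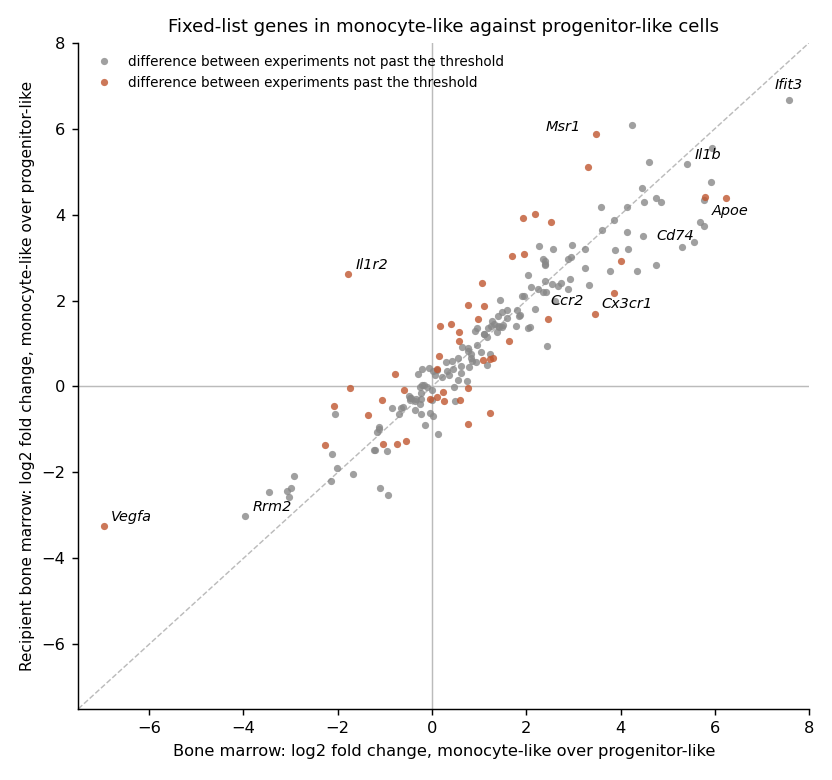
Log2 fold change of fixed-list genes, monocyte-like over progenitor-like cells, in native and recipient marrow. Il1b stood at 5.41 and 5.17, Il1r2 at −1.78 and 2.62, and Pfkfb4 at 1.70 and 3.03.

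The contrast between monocyte-like and progenitor-like cells differed between recipient and native marrow in glycolysis, among other lists. In recipients the excess of monocyte-like over progenitor-like cells was larger for Pfkfb4, Slc16a3 and Eno1, for the decoy receptor Il1r2, and for the integrin Itgam and the scavenger receptor Msr1. It was smaller for Nlrp3, Apoe, Cx3cr1 and Rsad2. Recipient library 3 held the lowest levels of Apoe and Cx3cr1 in classical-monocyte-like cells (24.1 and 24.3 CPM, medians of the others 166 and 142), and of Oasl2, Isg15, Irf7, Stat1 and Cd74. Without it the differences were −1.02 log2 for Apoe, −1.29 for Cx3cr1, −1.63 for Rsad2 and −0.85 for Nlrp3, each still past the threshold. An interaction term in edgeR over 213 list genes called 26 higher and 25 lower, and 30 and 34 adjusted over the list alone. Over all 11368 genes of that fit, 1026 were higher and 511 lower. Left-out libraries moved these counts: the higher count was 44 without recipient library 3, and the lower count was 16 without native library 1, 15 without native library 4, 10 without recipient library 2, 41 without recipient library 3 and 9 without recipient library 4. Experiment, reference, depth and transplantation differ together between the 2 arms, so no single one of them can be named as the source. Clusters were also named in each experiment by itself, into 17 classes in native and 11 in recipient marrow. The same class name may therefore cover other cells in the 2 experiments. Sex genes differ too in 3 of 4 recipient libraries, and no fit with a term for them was run.

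Of 19 glycolysis genes, 8 were higher, 0 lower and 11 not called in the interaction, 11 and 0 adjusted over the list alone (camera adjusted p = 9.2e-07; adjusted p = 0.0091 with an estimated correlation). Slc16a3 differed by 1.34 ± 0.17 log2 (1.06 native, 2.42 recipient; edgeR adjusted p = 7.3e-05), Pfkfb4 by 1.31 ± 0.16 and Eno1 by 0.56 ± 0.08. Of 12 MHC class II genes, 0 were higher, 2 lower and 10 not called, 0 and 6 adjusted over the list alone (camera adjusted p = 0.0039; adjusted p = 0.35 with an estimated correlation). H2-Ab1 differed by −1.82 ± 0.51 log2, but in 8 of 12 fits with 1 library left out it missed the threshold (−1.69 to −1.94 without native library 1, 3, 4, 6 or 7 or recipient library 2 or 4, −1.30 without recipient library 3). Without recipient library 3 the list missed it too (camera adjusted p = 0.052), and glycolysis passed at the preset correlation (1.4e-05) but not at the estimated one (0.082). Of 14 cholesterol genes, 0 were higher, 3 lower and 11 not called, 0 and 3 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.38 with an estimated correlation), with Hmgcs1 at −0.80 ± 0.14 log2. Of 25 immediate-early genes, 1 was higher, 6 lower and 18 not called, 1 and 8 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.35 with an estimated correlation), with Jund at −0.91 ± 0.21 log2. Of 24 interferon-stimulated genes, 0 were higher, 3 lower and 21 not called, 0 and 3 adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.59 with an estimated correlation), with Rsad2 at −1.82 ± 0.50 log2. This list rests on recipient library 3: without it the median was −0.03 log2 (camera adjusted p = 0.93), and it also missed the threshold without native library 2 (0.057) or 8 (0.059). Rsad2 missed it without native library 1 (−1.53) or 8 (−1.76) or recipient library 2 (−1.76). The other 7 lists did not pass camera with all libraries. Without recipient library 3, cell cycle passed at a median of −0.45 log2 (camera adjusted p = 0.00012; 0.33 with an estimated correlation), against 0.11 with it, and chemokine receptors and the IL-1 pathway passed too (0.032 each, and 0.33 and 0.26). Cytokine and NF-kB genes passed without recipient library 1 (0.031) or 2 (0.047), and scavenging genes without recipient library 1 (0.020), none of them with an estimated correlation (0.55, 0.57 and 0.38). The IL-1 pathway had 4 higher, 1 lower and 11 not called of 16, 7 and 1 adjusted over the list alone, and Il1r2 differed by 4.44 ± 0.44 log2 (edgeR adjusted p = 9.1e-06), among scavenging genes Msr1 by 2.34 ± 0.40. Chemokine receptors and adhesion genes had 6 higher, 2 lower and 8 not called of 16, 6 and 4 adjusted over the list alone, with Itgam at 1.97 ± 0.25 and Ccr1 at 1.83 ± 0.28. Higher and lower counts elsewhere were 1 and 2 of 17 for cell cycle, 1 and 2 of 17 for chromatin modifiers, 2 and 2 of 22 for NF-kB, 2 and 1 of 16 for matrix and 1 and 1 of 16 for scavenging. Cx3cr1 differed by −1.75 ± 0.40 log2, Apoe by −1.38 ± 0.34 (−1.34 and not called without recipient library 4) and Nlrp3 by −0.91 ± 0.19.

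Levels were also set side by side between the 2 marrow experiments without a test, counting the 231 list genes whose libraries did not overlap. In monocyte-like cells 6 were higher and 28 lower in recipients, and in progenitor-like cells 12 were higher and 24 lower. If the libraries of both experiments were interchangeable, 0.933 genes of 231 would separate so fully in either direction. They differ in reference, depth, sex genes and class naming, each of which could separate genes of any kind. Only list genes were counted, so the counts do not show that the lists stand out. In monocyte-like cells the lower set held 9 of 14 cholesterol genes, among them Ldlr (75.7 CPM native, 37.3 recipient) and Hmgcs1 (34.9 and 21.1). It also held Il1b, at 7.45 CPM native (5.88 to 19.9) and 1.05 recipient (0.632 to 3.18), Apoe (1029 and 186) and Nr4a1 (41.7 and 9.38). The higher set there held Nfkbia (134 and 221), Tlr4 (10.6 and 14.02) and Pcna (32.7 and 84.8). In progenitor-like cells 6 interferon-stimulated genes were higher in recipients, among them Bst2 (96.0 and 202) and Isg15 (3.62 and 11.6). Lower there were Fn1 (229 and 41.2), Cd9 (81.5 and 13.4), Itgam (72.8 and 16.9), Eno1 (310 and 137) and Slc16a3 (21.6 and 6.61). Part of the larger contrast in recipients therefore comes from lower progenitor-like levels. Glycolysis genes without overlap were 0 higher and 3 lower in recipient monocyte-like cells, and 0 and 5 in progenitor-like cells. By this count the larger glycolysis contrast cannot be read as a rise in recipient monocyte-like cells. Fewer libraries can only hold or raise such counts, and with 3 recipient libraries chance gives 2.80 genes. Without recipient library 3 the counts were 17 higher and 44 lower in monocyte-like cells and 20 and 37 in progenitor-like cells. Without recipient library 1 the monocyte-like higher count was 11.

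The recipient reference also holds an EGFP sequence, and its UMIs were unevenly spread over classes. The median was 962 CPM in nonclassical-monocyte-like cells (546 to 1021), 733 in B-cell-like cells (618 to 935), 654 in classical-monocyte-like cells (531 to 774) and 570 in neutrophil-like cells. It was 193 CPM in NK-cell-like cells, 166 in granulocyte-monocyte-progenitor-like cells and 58.3 in erythroid-like cells. Per cell the order differs: medians were 9.26 EGFP UMIs in classical-monocyte-like, 6.396 in progenitor-like, 2.47 in B-cell-like, 2.07 in erythroid-like and 1.43 in NK-cell-like cells. With cells thinned to equal depth, 69.5% of classical-monocyte-like, 66.4% of B-cell-like, 24.9% of progenitor-like and 14.6% of erythroid-like cells held an EGFP UMI. The labels do not state which animals carried the transgene. The X-inactivation transcript Xist had medians of 0 CPM in classical-monocyte-like cells of the native marrow and of the periphery, where the Y-chromosome gene Ddx3y stood at 49.1 and 58.1 CPM. In recipients Xist stood at 529, 777 and 448 CPM in libraries 1, 3 and 4 and at 1.14 CPM in library 2, whose Ddx3y stood at 49.9 CPM.

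**Figure D4:**
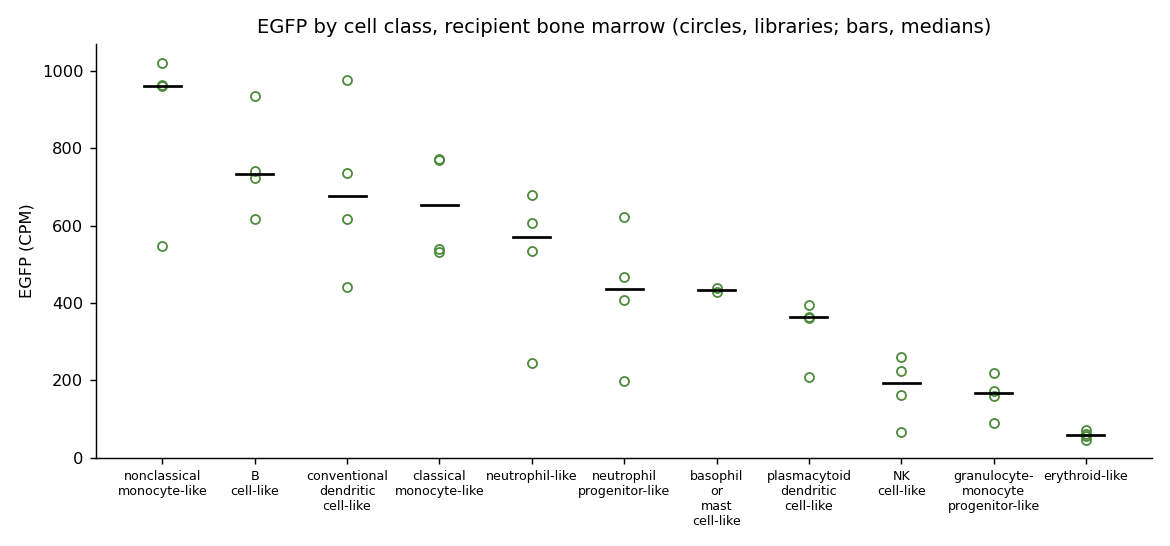
EGFP by class in recipient marrow. Median levels ranged from 58.3 CPM in erythroid-like cells to 962 CPM in nonclassical-monocyte-like cells.

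Hashtags divided the peripheral cells into parts with their own class make-up. B0301 marked 1392 cells, a median of 3.46% of a library, and held 518 of 560 cardiac-resident-macrophage-like cells. B0302, B0303 and B0304 marked 7581, 7522 and 7998 cells, and 12403 cells had none. Untagged cells held 333 of 348 red-pulp-macrophage-like cells, 336 of 392 erythroid-like cells and 913 of 1336 B-cell-like cells. Classical-monocyte-like cells made up medians of 29.1, 24.3 and 15.4% of B0302, B0303 and B0304, and neutrophil-like cells 11.3, 14.5 and 22.2%. RNA of marker sets and of other cells was set side by side without a test. The cardiac-resident-macrophage set had a median of 4039 CPM in B0301 (673 to 8030), against 631, 540 and 398 in B0302 to B0304. The Kupffer-cell set stood at 542 CPM in B0301 (96.0 to 1203), against 35.6, 34.4 and 90.3. Cells with B0301 also held 164 CPM of cardiomyocyte RNA, 538 of hepatocyte RNA and 1713 of platelet RNA. In B0302 to B0304 these stood at 33.6, 35.1 and 32.3, at 144, 152 and 118, and at 36.6, 34.9 and 53.8 CPM. The alveolar-macrophage marker set stood at 801, 520 and 452 CPM in B0302, B0303 and B0304, with overlapping ranges (344 to 2681, 327 to 1503 and 223 to 1495). Lung-epithelium RNA stood at 707, 489, 429 and 422 CPM in B0301 to B0304 and at 355 CPM in untagged cells. Its ranges in B0302 to B0304 overlapped too (406 to 618, 289 to 560 and 329 to 667).

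Classical-monocyte-like cells of B0302 were compared with those of the other 2 hashtags within the 8 libraries. They held less of the early-response genes Fosb, Fos and Ier3, less of the chemokines Cxcl2 and Ccl3, and less Il1b and Tnf, a program that monocytes switch on within minutes to hours of a stimulus or of tissue dissociation. Ccr2, Cx3cr1, the histone Hist1h1e and the actin crosslinker Flna were higher. Of 8937 genes, 744 were higher and 861 lower by edgeR, 18 and 113 of them at least 2-fold. Of 195 list genes, 9 were higher and 80 lower, and 12 and 88 adjusted over the list alone. Within libraries, cluster 2 held medians of 88.0, 81.3 and 89.5% of these cells in B0302, B0303 and B0304, and cluster 12, led by Cxcl9 and Cxcl10, held 9.81, 16.1 and 9.85% and was highest in B0303 in 8 of 8 libraries. Cluster 11 comes almost wholly from library 5, where it held 78.8, 83.0 and 76.3%. The 3 comparisons of a hashtag with the other 2 use the same cells and are linked. Each gene given a log2 value in these comparisons, and in those of neutrophil-like cells, moved the same way in 8 of 8 libraries unless noted.

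In B0302, 21 of 25 immediate-early genes were lower, 1 higher and 3 not called, 21 and 1 adjusted over the list alone (camera adjusted p = 1.1e-29, and 0.0027 with an estimated correlation). Ier3 fell by 3.76 ± 0.18 log2 (edgeR adjusted p = 5.5e-10; medians 7.15 CPM in B0302, 88.8 in B0303 and 161 in B0304), Fosb by 3.16 ± 0.24 (4.89, 22.8 and 111) and Fos by 2.09 ± 0.20 (202, 558 and 1525). Of 24 cytokine and NF-kB genes, 19 were lower, 1 higher and 4 not called, 21 and 1 adjusted over the list alone (camera adjusted p = 3.1e-21, and 0.00092 with an estimated correlation). Cxcl2 fell by 4.59 ± 0.50 log2 (1.07, 22.3 and 35.9 CPM) and Ccl3 by 2.98 ± 0.21 (5.11, 30.8 and 45.7). Tnf fell by 2.34 ± 0.14 log2 (4.65, 24.0 and 20.6 CPM). Of 14 IL-1 pathway genes, 7 were lower, 0 higher and 7 not called, 7 adjusted over the list alone (camera adjusted p = 0.0032, and 0.040 with an estimated correlation). Il1b fell by 1.63 ± 0.18 log2 (46.8, 128 and 214 CPM; edgeR adjusted p = 7.3e-06) and Nlrp3 by 0.62 ± 0.06 (42.6, 59.0 and 74.1). Glycolysis genes were 10 lower, 0 higher and 9 not called of 19 (13 and 1 adjusted over the list alone; camera adjusted p = 6.0e-05; adjusted p = 0.12 with an estimated correlation), with Tpi1 at −0.35 ± 0.08 log2. MHC class II genes were 4 lower, 0 higher and 7 not called of 11 (5 and 0 adjusted over the list alone; camera adjusted p = 6.0e-05; adjusted p = 0.12 with an estimated correlation), with Cd86 at −0.62 ± 0.08 log2. Higher and lower counts in the lists that did not pass camera were 0 and 1 of 7 for cell cycle, 3 and 4 of 14 for chemokine receptors and adhesion, 1 and 2 of 13 for cholesterol synthesis, 0 and 3 of 17 for chromatin modifiers, 3 and 3 of 24 for interferon-stimulated genes, 0 and 4 of 14 for matrix and 0 and 2 of 14 for scavenging. Hist1h1e rose by 1.56 ± 0.07 log2 (50.7, 16.3 and 18.8 CPM), Flna by 0.43 ± 0.03 and Ccr2 by 0.22 ± 0.02 (1916, 1676 and 1589).

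In classical-monocyte-like cells of B0303, the chemokines Cxcl9 and Cxcl10 and the GTPase Gbp2, which interferon gamma induces in macrophages, were higher than in the other 2 hashtags, together with Il1rn, the IL-1 receptor antagonist, and Socs3. The complement gene C1qb was higher as well, and Ace, a gene of patrolling monocytes, was lower. Of 8937 genes, 279 were higher and 148 lower by edgeR, 50 and 4 of them at least 2-fold. Without library 8 the counts were 178 and 93, and without library 7 the lower count was 94. Of 195 list genes, 48 were higher and 7 lower, and 71 and 11 adjusted over the list alone.

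Cxcl9 rose in B0303 by 4.95 ± 0.32 log2 (3.12, 169 and 10.3 CPM in B0302, B0303 and B0304; edgeR adjusted p = 1.3e-07), Cxcl10 by 2.51 ± 0.26 (42.4, 315 and 52.5) and C1qb by 2.16 ± 0.31. Of 24 cytokine and NF-kB genes, 16 were higher, 1 lower and 7 not called, 21 and 1 adjusted over the list alone (camera adjusted p = 6.6e-21, and 0.00092 with an estimated correlation). Of 24 interferon-stimulated genes, 6 were higher, 1 lower and 17 not called, 12 and 1 adjusted over the list alone (camera adjusted p = 1.5e-07; adjusted p = 0.096 with an estimated correlation). Gbp2 rose by 1.48 ± 0.21 log2 (49.6, 139 and 47.5 CPM), in 7 of 8 libraries. Of 19 glycolysis genes, 11 were higher, 0 lower and 8 not called, 13 and 0 adjusted over the list alone (camera adjusted p = 7.6e-11, and 0.017 with an estimated correlation), with Pfkp at 0.44 ± 0.07 log2. Of 14 IL-1 pathway genes, 2 were higher, 0 lower and 12 not called, 2 adjusted over the list alone (camera adjusted p = 0.00018, and 0.015 with an estimated correlation). Il1rn rose by 1.39 ± 0.12 log2 (9.28, 24.5 and 9.85 CPM), and Il1b was not called. Of 11 MHC class II genes, 3 were higher, 0 lower and 8 not called, 9 and 0 adjusted over the list alone (camera adjusted p = 2.7e-07, and 0.042 with an estimated correlation), with Cd40 at 0.56 ± 0.08 log2. Immediate-early genes were 4 higher, 2 lower and 19 not called of 25 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0014; adjusted p = 0.35 with an estimated correlation), with Socs3 at 1.26 ± 0.15 log2. The lists short of the camera threshold had higher and lower counts of 0 and 0 of 7 for cell cycle, 1 and 2 of 14 for chemokine receptors and adhesion, 1 and 0 of 13 for cholesterol synthesis, 1 and 0 of 17 for chromatin modifiers, 1 and 0 of 14 for matrix and 2 and 1 of 14 for scavenging. Ace fell by 0.71 ± 0.13 log2 (86.4, 58.0 and 94.1 CPM) and Cx3cr1 by 0.13 ± 0.03.

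Classical-monocyte-like cells of B0304 held the most early-response RNA. Fosb, Fos, Dusp1 and Ier3 were higher, and with them Cxcl2, Il1b, the matrix protein Thbs1 and the retention receptor Cxcr4. Il1rn, the dendritic-type lectin Cd209a, Flna and Ccr2 were lower. Of 8937 genes, 680 were higher and 457 lower by edgeR, 80 and 12 of them at least 2-fold. Of 195 list genes, 53 were higher and 15 lower, and 61 and 22 adjusted over the list alone. Of 25 immediate-early genes, 21 were higher, 0 lower and 4 not called, 22 and 1 adjusted over the list alone (camera adjusted p = 3.1e-27, and 0.0080 with an estimated correlation). Fosb rose by 3.26 ± 0.18 log2 (edgeR adjusted p = 2.9e-09), Dusp1 by 2.49 ± 0.20 (68.8, 154 and 551 CPM in B0302, B0303 and B0304) and Ier3 by 2.47 ± 0.14.

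Of 24 cytokine and NF-kB genes in B0304, 13 were higher, 3 lower and 8 not called, 15 and 4 adjusted over the list alone (camera adjusted p = 1.5e-06; adjusted p = 0.064 with an estimated correlation). Cxcl2 rose by 2.80 ± 0.38 log2 and Ccl3 by 1.85 ± 0.17. Il1b rose by 1.33 ± 0.16 log2 (edgeR adjusted p = 3.4e-05), Cxcr4 by 1.27 ± 0.13 (33.04, 49.1 and 105 CPM) and Thbs1 by 1.38 ± 0.25 (5.21, 9.44 and 26.7). IL-1 pathway genes were 2 higher, 3 lower and 9 not called of 14, 3 and 4 adjusted over the list alone, among them Nlrp3 at 0.57 ± 0.06 log2 and Il1rn at −0.63 ± 0.16. Interferon-stimulated genes were 0 higher, 3 lower and 21 not called of 24, 0 and 3 adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.65 with an estimated correlation). Lists that camera did not call had higher and lower counts of 2 and 0 of 7 for cell cycle, 4 and 1 of 14 for chemokine receptors and adhesion, 1 and 0 of 13 for cholesterol synthesis, 1 and 0 of 17 for chromatin modifiers, 1 and 3 of 19 for glycolysis, 4 and 1 of 14 for matrix, 2 and 0 of 11 for MHC class II and 2 and 1 of 14 for scavenging. Flna fell by 0.46 ± 0.03 log2, Cd209a by 0.52 ± 0.13 and Ccr2 by 0.15 ± 0.02, while Cx3cr1 was not called. None of the other-cell lists passed camera in any of the 3 monocyte comparisons.

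**Figure D5:**
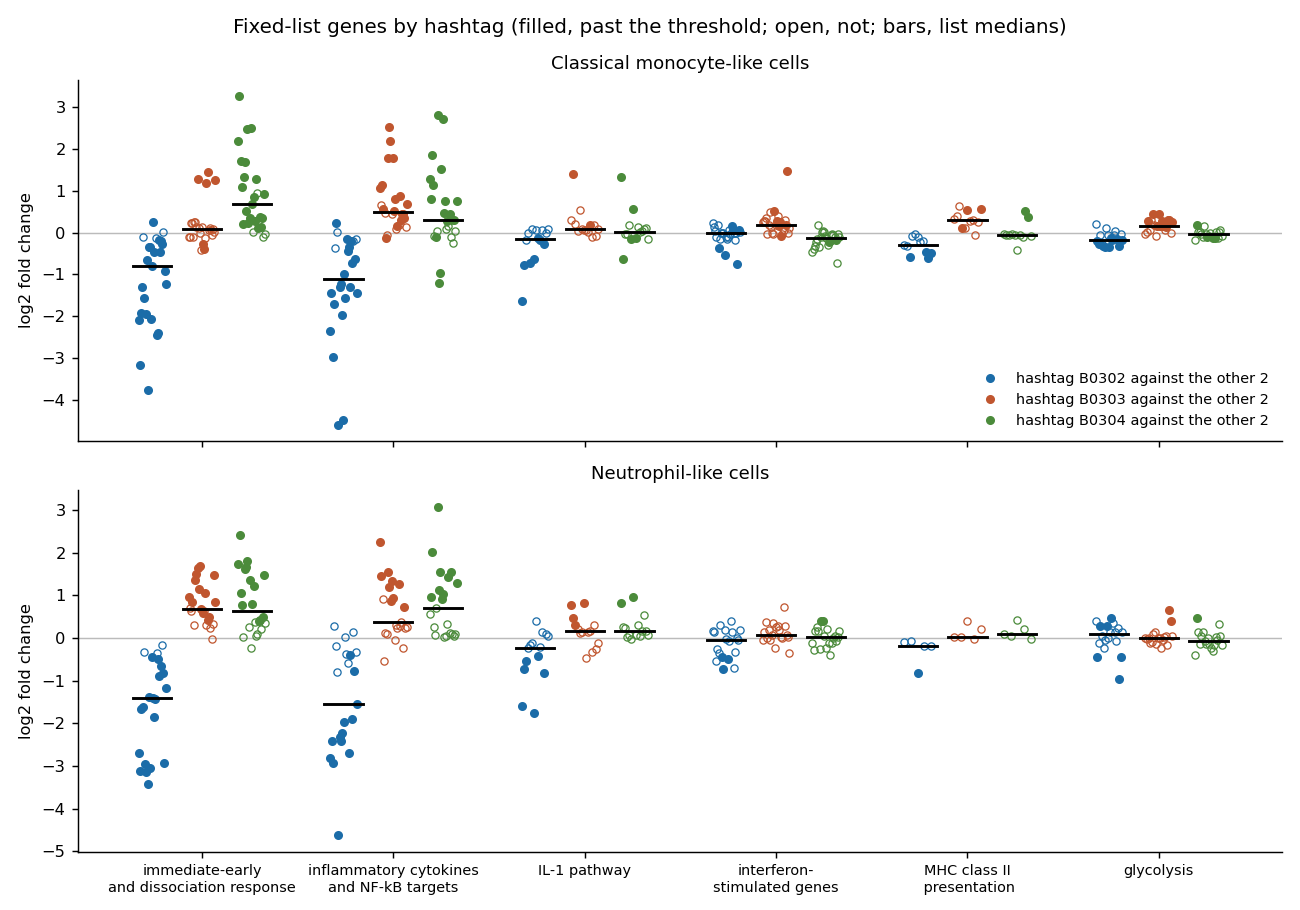
Fixed lists over the 3 hashtags in classical-monocyte-like and neutrophil-like cells. Immediate-early genes were 21 lower of 25 in B0302 monocyte-like cells and 19 lower of 22 in B0302 neutrophil-like cells.

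Neutrophil-like cells of B0302 also held less of the early-response genes, in a fit of their own that was not compared with the monocyte-like cells. Cxcl2, Il1b, Ier3, Atf3, Nlrp3 and the niacin receptor Hcar2 were lower than in the other 2 hashtags, all genes that activated neutrophils raise, and the ubiquitin ligase Rnf141 and the splicing factor Zfp207 were higher. Of 4628 genes, 350 were higher and 424 lower by edgeR, 18 and 115 of them at least 2-fold. The higher count was 227 without library 3, 160 without library 4 and 201 without library 7. Within libraries, cluster 4 held medians of 93.8, 97.5 and 95.9% of these cells in B0302, B0303 and B0304. Cluster 21, led by the granule genes Ltf, Ngp and Camp, held medians of 3.35, 1.20 and 1.81%, with 38.4 and 26.9% in B0302 of libraries 4 and 7. Of 143 list genes, 4 were higher and 54 lower, and 7 and 62 adjusted over the list alone. Immediate-early genes were 19 lower, 0 higher and 3 not called of 22, 21 and 0 adjusted over the list alone (camera adjusted p = 2.7e-29, and 0.0056 with an estimated correlation), with Ier3 at −3.05 ± 0.13 log2 (edgeR adjusted p = 2.0e-15; 111, 920 and 836 CPM) and Atf3 at −3.42 ± 0.22 (32.7, 350 and 366).

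Of 21 cytokine and NF-kB genes in B0302 neutrophil-like cells, 13 were lower, 0 higher and 8 not called, 16 and 0 adjusted over the list alone (camera adjusted p = 2.5e-16, and 0.0027 with an estimated correlation). Cxcl2 fell by 4.62 ± 0.52 log2 (36.6, 926 and 2515 CPM in B0302, B0303 and B0304) and Tnfaip3 by 2.70 ± 0.25 (12.4, 80.1 and 87.2). Of 14 IL-1 pathway genes, 6 were lower, 0 higher and 8 not called, 6 and 0 adjusted over the list alone (camera adjusted p = 0.00039, and 0.013 with an estimated correlation). Il1b fell by 1.58 ± 0.17 log2 (3731 CPM in B0302; edgeR adjusted p = 3.6e-06) and Nlrp3 by 1.76 ± 0.19 (158, 475 and 523). Matrix genes were 3 lower, 1 higher and 7 not called of 11, 3 and 1 adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.055 with an estimated correlation), with Vegfa at −1.90 ± 0.25 log2 (11.1, 47.0 and 72.4 CPM). Chemokine receptors were 3 lower, 0 higher and 9 not called of 12, 5 and 0 adjusted over the list alone (camera adjusted p = 0.049; adjusted p = 0.27 with an estimated correlation), with Cxcr4 at −0.68 ± 0.09 log2. Higher and lower counts in the lists that did not pass camera were 0 and 1 of 2 for cell cycle, 0 and 0 of 1 for cholesterol synthesis, 0 and 2 of 12 for chromatin modifiers, 3 and 3 of 18 for glycolysis, 0 and 3 of 19 for interferon-stimulated genes, 0 and 1 of 5 for MHC class II and 0 and 0 of 6 for scavenging. Rnf141 rose by 1.24 ± 0.16 log2 (84.4, 36.4 and 30.4 CPM) and Zfp207 by 0.99 ± 0.12.

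Neutrophil-like cells of B0303 held more Tnf, Ier3 and Csrnp1 than the mean of the other 2 hashtags, of which B0302 was low. They also held more of the NF-kB inhibitors Nfkbia and Nfkbid, genes that NF-kB itself induces. The actin-binding gene Tmsb10 was lower. Of 4628 genes, 185 were higher and 24 lower by edgeR, 26 and 3 of them at least 2-fold. The lower count was 10 without library 3 and 13 without library 5 or library 7. Of 143 list genes, 36 were higher and 0 lower, and 42 and 0 adjusted over the list alone. Tnf rose by 2.25 ± 0.29 log2 (13.6, 155 and 61.7 CPM in B0302, B0303 and B0304; edgeR adjusted p = 8.7e-05), Ier3 by 1.69 ± 0.10, Nfkbid by 1.65 ± 0.11 (58.0, 326 and 201) and Nfkbia by 1.33 ± 0.11 (227, 1174 and 891). Il1b was 0.77 ± 0.15 log2 above the mean of the other 2 (edgeR adjusted p = 0.0048), which reflects the low B0302 (3731, 9960 and 9959 CPM), and Tmsb10 fell by 0.88 ± 0.14 (206, 87.4 and 131 CPM). Immediate-early genes were 14 higher, 0 lower and 8 not called of 22, 21 and 0 adjusted over the list alone (camera adjusted p = 1.8e-25, and 0.0098 with an estimated correlation). Here too B0302 was low. In B0302, B0303 and B0304 Ier3 stood at 111, 920 and 836 CPM, Atf3 at 32.7, 350 and 366 and Egr2 at 2.21, 41.9 and 41.8. Cytokine and NF-kB genes were 9 higher, 0 lower and 12 not called of 21, 9 and 0 adjusted over the list alone (camera adjusted p = 4.6e-11, and 0.0098 with an estimated correlation). Among them Cxcl2 stood at 36.6, 926 and 2515 CPM, higher in B0304 than in B0303. IL-1 pathway genes were 4 higher, 0 lower and 10 not called of 14, 4 and 0 adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.091 with an estimated correlation). Matrix genes were 2 higher, 0 lower and 9 not called of 11, 2 and 0 adjusted over the list alone, led by Tgfb1 at 0.68 ± 0.11 log2 (camera adjusted p = 0.039; adjusted p = 0.091 with an estimated correlation). Chemokine receptors were 3 higher, 0 lower and 9 not called of 12, 4 and 0 adjusted over the list alone, with Ccr1 at 0.46 ± 0.09 log2 (camera adjusted p = 0.039; adjusted p = 0.23 with an estimated correlation). The lists short of the camera threshold had higher and lower counts of 0 and 0 of 2 for cell cycle, 0 and 0 of 1 for cholesterol synthesis, 2 and 0 of 12 for chromatin modifiers, 2 and 0 of 18 for glycolysis, 0 and 0 of 19 for interferon-stimulated genes, 0 and 0 of 5 for MHC class II and 0 and 0 of 6 for scavenging.

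Neutrophil-like cells of B0304 held the highest Cxcl2, Hcar2 and Slc7a11, the cystine importer that rises in aged or activated neutrophils. Icam1, Ptgs2 and Vegfa were higher too. Of 4628 genes, 179 were higher and 37 lower by edgeR, 61 and 2 of them at least 2-fold. The lower count was 15 without library 2, 24 without library 3, 22 without library 5, and 20 without library 6 or library 8. Of 143 list genes, 33 were higher and 0 lower, and 39 and 1 adjusted over the list alone. Cxcl2 rose by 3.07 ± 0.39 log2 (edgeR adjusted p = 0.00012), Hcar2 by 2.48 ± 0.20, Slc7a11 by 1.85 ± 0.12 (292, 1288 and 2205 CPM in B0302, B0303 and B0304), Icam1 by 1.53 ± 0.19 (20.8, 47.5 and 81.6), Ptgs2 by 1.55 ± 0.18 and Il1b by 0.82 ± 0.15 (edgeR adjusted p = 0.0023), at the level of B0303 (9959 and 9960 CPM). Immediate-early genes were 14 higher, 0 lower and 8 not called of 22, 16 and 1 adjusted over the list alone (camera adjusted p = 2.1e-21, and 0.013 with an estimated correlation). Fos (812, 3675 and 5759 CPM) and Fosb (64.9, 387 and 822) were highest in B0304. Atf3 (32.7, 350 and 366) and Egr2 (2.21, 41.9 and 41.8) stood near B0303, so their rise reflects the low B0302. Cytokine and NF-kB genes were 10 higher, 0 lower and 11 not called of 21, 11 and 0 adjusted over the list alone (camera adjusted p = 7.4e-15, and 0.0042 with an estimated correlation). IL-1 pathway genes were 2 higher, 0 lower and 12 not called of 14, 6 and 0 adjusted over the list alone (camera adjusted p = 0.00032, and 0.013 with an estimated correlation). Lists that camera did not call had higher and lower counts of 0 and 0 of 2 for cell cycle, 1 and 0 of 12 for chemokine receptors and adhesion, 0 and 0 of 1 for cholesterol synthesis, 1 and 0 of 12 for chromatin modifiers, 1 and 0 of 18 for glycolysis, 2 and 0 of 19 for interferon-stimulated genes, 2 and 0 of 11 for matrix, 0 and 0 of 5 for MHC class II and 0 and 0 of 6 for scavenging. Neutrophil RNA as a list stood lower in B0304, with a median log2 of −0.54 (camera adjusted p = 0.024; adjusted p = 0.77 with an estimated correlation). No other-cell list passed camera in B0302 or B0303 neutrophil-like cells.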

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

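The test of EGFP against free RNA, that of the genes lower in recipient library 3, the lists with a library left out and all values by Xist and Y-chromosome genes were chosen after the result was seen. The other tests here were written before the values they measure were seen.

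Per-library values in 70 groups were checked for a library far from the rest. In 5 groups 1 library stood apart, where chance alone marks about 1 in 20 groups, or 3.5. Libraries of control and stroke samples, which cannot be told apart here, share each group. Plasma-cell-like cells made up 1.46% of peripheral library 8, against 0.0707 to 0.346% in the other 7. Neutrophil-like cells made up 3.52% of recipient library 1, against 1.46 to 1.80%. Ccr2 in peripheral classical-monocyte-like cells was 1327 CPM in library 6, against 1676 to 1859, and Il1b there was 73.1 CPM in library 6, against 110 to 135. Cx3cr1 in the same class was 235 CPM in library 5, against 493 to 677.

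The monocyte-progenitor contrast differed between recipient and native marrow in 5 lists by the interaction term. The median difference was 0.29 log2 for glycolysis, −0.21 for cholesterol synthesis, −0.29 for immediate-early genes, −0.30 for interferon-stimulated genes and −0.50 for MHC class II genes. Glycolysis alone passed camera with an estimated correlation as well, though not without recipient library 3 (adjusted p = 0.082). Without that library the interferon-stimulated list stood at −0.03 (camera adjusted p = 0.93) and MHC class II missed the threshold (0.052), while cell cycle (median −0.45, adjusted p = 0.00012, against 0.11 with it), chemokine receptors and the IL-1 pathway (0.032 each) passed, though not with an estimated correlation (0.33, 0.33 and 0.26). Cytokine and NF-kB genes passed without recipient library 1 (0.031) or 2 (0.047) and scavenging genes without recipient library 1 (0.020), again not with an estimated correlation. The interferon-stimulated list also missed it without native library 2 (0.057) or 8 (0.059). Of 50 splits of the 12 libraries into 8 and 4, 1, the real one, gave as many list genes as the real 51. The highest of the others gave 0. The real split follows 2 experiments processed and named separately, so this outcome was all but fixed in advance. No conclusion on chance is drawn from it. Transplantation, sex genes, depth, reference and the naming of classes within each experiment differ with that split and stay open.

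Peripheral library 5 also holds a monocyte-like state of its own. Cluster 11 has 980 cells, 95.1% of them from library 5, and 9 genes stood at least 2-fold above every other library, among them Lcn2 (94.2 CPM, median of the others 4.46), Vcan (766 and 101), Prtn3 (107 and 15.8) and S100a8 (323 and 49.99), while Cd74 (867 and 2774) and Cx3cr1 stood below. Another mix of hashtags is argued against, since within B0302, B0303 and B0304 the median difference of these genes was at least 0.976 of the overall one. RNA shared by all cells of the library stays open: NK-cell-like cells showed 0.462 of the difference, between the bounds of 0.25 and 0.5 set in advance. B-cell-like cells showed 0.629, nonclassical-monocyte-like cells 0.674, conventional-dendritic-cell-like cells 0.811 and neutrophil-like cells 0.0882. No biological explanation was tested, since the library cannot be tied to a group.

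Recipient library 3 has 289 genes at least 2-fold above the other 3 libraries in classical-monocyte-like cells, among them 16 of the 17 cell-cycle list genes, such as Top2a (809 CPM, median of the others 36.0), and 113 at least 2-fold below, 21 of them in the fixed lists, led by Apoe (24.1 and 166), Oasl2 (22.6 and 147), Cx3cr1 (24.3 and 142) and Isg15 (29.0 and 147), with Cd74, Irf7 and Stat1. RNA shared by the whole library is argued against, since in B-cell-like cells the 289 genes moved by −0.0345 of that difference and the 113 by 0.134 (0.0194 over the 51 at 50 CPM or more there). Lcn2 and Prtn3 were raised in both single-library states, 2 shared genes. Among the 2855 genes that reached 50 CPM in some library of both experiments stand 7 of the 9 and 61 of the 289, and independent sets of those sizes would share 0.150, a ratio of 13.4. With so few expected, any shared gene at all would pass the bound set in advance. Chance overlap therefore cannot be judged from these 2 genes. How clusters were named stays open, untested: clusters 19 and 21, led by Ccne2 and by Vcan, Mmp8 and Top2a, took the monocyte name and come 94.98 and 98.0% from library 3, while clusters 5, 7 and 10, led by histone, replication and mitosis genes, took none. Unnamed cells made up 3.43% of library 3 and 18.0 to 36.2% of the others. No biological explanation was tested here either.

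EGFP UMIs were counted in the recipient matrix, where no comparison used them, at a median of 654 CPM in classical-monocyte-like cells. Free RNA alone would give each cell of a library a similar number whatever its class. Classical-monocyte-like cells instead held 3.24 times as many EGFP UMIs per cell as B-cell-like cells in the median library (2.49, 3.0, 5.03 and 3.48 in libraries 1 to 4), which argues against free RNA as the only source. In recipient library 2, NK-cell-like cells with Xist UMIs and no Y-chromosome UMIs had 46.8 CPM of EGFP (38 cells), and those with Y-chromosome UMIs and no Xist had 687 CPM (12 cells). The labels name neither the animals that carry EGFP nor the sex of donors and recipients, so no biological explanation was tested.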

How the results depend on the processing

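The tests of hashtags, of the interaction and without clusters from a single library were chosen after seeing the data, those of hashtags before any expression value by hashtag was seen. Of the counts and shares under alternatives and left-out libraries, 575 values stayed within 1.5 times or within the spread between libraries and 84 did not. Of the named-gene values, 5462 kept direction and side of the threshold, 371 kept direction and lost the threshold, 2 gained it and 3 reversed. DESeq2 size factors, at least 1000 UMIs per cell, a hashtag share of 80%, marker genes left out of the lists and removal of other-cell genes moved no count by 1.5 times. Settings planned for stroke against control and for organs by name were not run. Simulated data gave back 25.3% of genes at 1.5-fold in recipient marrow, which has the most UMIs per pseudobulk (at least 16.2e6) but 3 residual degrees of freedom and a biological coefficient of variation of 0.196.

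In equal cells of equal depth, which leaves far fewer UMIs, list genes in the marrow contrast were 35 higher and 20 lower in native and 85 and 23 in recipient marrow, and 7 and 7 in the interaction. Classical-monocyte-like counts were 12 and 47 in B0302, 6 and 1 in B0303, and 43 and 8 in B0304. Neutrophil-like counts were 11 and 44, 27 and 1, and 20 and 1. Non-overlapping genes between recipients and native marrow were 6 lower in monocyte-like cells, and 5 higher and 8 lower in progenitor-like cells. Cx3cr1 in B0303 monocyte-like cells went to 0.024 log2, Mmp8 in B0304 monocyte-like cells to 0.074 and Tln1 in B0304 neutrophil-like cells to 0.10, each reversed. A floor of 50 CPM, which tests fewer genes, gave 76 higher and 32 lower in native and 73 and 29 in recipient marrow, 526 lower in B0302 and 150 higher in B0303 monocyte-like cells. Without the library block, that is without pairing, recipient list genes were 29 lower. Monocyte-like counts were then 184 higher and 290 lower in B0302, 56 and 7 in B0303, and 211 and 72 in B0304, and neutrophil-like counts 94 higher and 10 lower in B0303 and 12 lower in B0304. The block moved no other count by 1.5 times.

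For the settings that follow the cause was not tested. The DESeq2 Wald test gave 485 higher in B0302 and 98 lower in B0303 monocyte-like cells. At least 50 cells, which leaves 6 of 8 libraries, gave 217 higher in B0302 and 116 higher and 17 lower in B0304 neutrophil-like cells. No low-count filter gave 46 lower in B0303, and 333 higher and 21 lower in B0304 neutrophil-like cells, and 15 lower in the interaction, and doublets kept gave 23 lower in B0304. Without single-library clusters, the interaction had 41 higher and the monocyte-like comparison of recipient with native marrow 14 higher. Leiden resolution 0.5 put classical-monocyte-like cells at 25.99% of marrow. With the estimated correlation 0 of 9 lists passed camera in native and 0 of 8 in recipient marrow, 3 of 5, 4 of 6 and 1 of 3 in B0302, B0303 and B0304 monocyte-like cells, 3 of 5, 2 of 5 and 3 of 3 in neutrophil-like cells and 1 of 5 in the interaction.

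Leaving out 1 library gave 132 to 139 higher and 47 to 51 lower in native marrow. Recipient lower counts ran from 24 (without library 4; 25 without library 2) to 58. B0303 monocyte-like counts ran from 178 (without library 8) to 297 higher and from 93 (without library 8; 94 without library 7) to 160 lower. B0302 neutrophil-like higher counts ran from 160 (without library 4; 201 without 7, 227 without 3) to 329. Lower counts of neutrophil-like cells ran from 10 (without library 3; 13 without 5 or 7) to 24 in B0303 and from 15 (without library 2; 20 without 6 or 8, 22 without 5, 24 without 3) to 37 in B0304. The interaction ran from 20 to 44 higher (44 without recipient library 3) and from 9 to 41 lower (9, 10 and 41 without recipient libraries 4, 2 and 3, 15 and 16 without native libraries 4 and 1). Between recipient and native marrow, monocyte-like counts ran from 6 to 17 higher (17 without recipient library 3, 11 without 1) and 28 to 44 lower, and progenitor-like counts from 12 to 20 higher and 24 to 37 lower, each highest without recipient library 3, where fewer libraries can only hold or raise these counts.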

Other observations

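The test of neutrophil RNA behind Il1b, the sex-gene values and the levels by cluster were chosen after the result was seen, and so was the bound that set aside the immediate-early covariate. The other tests were written before the values they measure were seen.

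Transcripts of Il1b and Il1r1 were highest in different classes among those read for list genes, which leave out T-cell-like and some other classes. Among the peripheral classes read, Il1b was highest in neutrophil-like cells at 8267 CPM, where Il1r1 had a median of 0. Among the marrow classes read, Il1r1 was highest in stem-and-multipotent-progenitor-like cells at 25.3 CPM (12.2 to 29.4), with 0.874 CPM in granulocyte-monocyte-progenitor-like cells. Recipient granulocyte-monocyte-progenitor-like cells held 2.02 CPM of Il1r1 (1.43 to 2.59). Peripheral cluster 23, 142 cells without a class, combined Il1b, Cxcl2 and Hcar2 among its leading genes with 9 of 9 nonclassical-monocyte markers.

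Sex genes set the recipient libraries apart from each other and from the native ones. In native marrow and peripheral libraries Xist reached at most 0.0839 CPM in classical-monocyte-like cells, and Ddx3y ranged from 43.4 to 59.9 and from 50.9 to 64.6 CPM. In recipient libraries 1, 3 and 4 Xist stood at 529, 777 and 448 CPM with Ddx3y at 0, 0.153 and 0 CPM. In recipient library 2 classical-monocyte-like cells had Ddx3y at 49.9 CPM and Xist at 1.14, while its NK-cell-like cells had Xist at 829 CPM beside Ddx3y at 33.1. Native marrow and 3 of 4 recipient libraries thus differ in these genes, while classical-monocyte-like cells of recipient library 2 resemble native marrow in them, and no fit with a term for sex genes was run.

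Early-response RNA was lower in B0302 than in B0303 and B0304 in monocyte-like and in neutrophil-like cells, each in its own fit. For Il1b in the monocyte-like cells, RNA from neutrophils is argued against: the excess over B0302 would need 0.857 and 1.55% of neutrophil RNA, which would bring 688 and 1146 CPM of S100a8, where 4.15 and 3.98 were observed, a median ratio of 0.00222 over both S100 genes. A difference of depth or cell number cannot be judged. In equal cells of equal depth, fold changes of classical-monocyte-like cells stood at a median of 0.960 of their size. Cells and UMIs were drawn at random, which keeps expected proportions, so a ratio near full size was all but fixed in advance. RNA from other sorted cell types stays open, since 82 of 1703 higher calls (4.82%) were genes that such RNA could only dilute. The dissociation response cannot be told apart: with the immediate-early mean as a covariate 6.22% of calls stayed, each of them in B0303 (197 of 427), but library and hashtag explain 96.2% of that covariate, and no biological explanation was tested, since the codes name no organ.

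Splits that exchanged arms within libraries were counted for each comparison. In native marrow 1 of 100 splits, the real one, gave as many list genes as the real 187, and the highest other gave 157. The arms were separated by clustering the expression of the same cells, so this outcome was all but fixed in advance. No conclusion on chance is drawn from it. Recipient marrow, where the same limit applies, allows 8 splits, too few for a share under 0.05, with the real value 176 and the highest other 0. For B0302, B0303 and B0304 against the other 2, 1 of 100 splits, the real one, gave as many genes in each case. Monocyte-like counts were 1605 against 37 in the highest other split, 427 against 35 and 1137 against 2. Neutrophil-like counts were 774 against 2, 209 against 1 and 216 against 1. Chance can therefore be excluded for a difference among the hashtags in each of these classes. All hashtags were exchanged together and the comparisons are linked, so the counts do not test each hashtag by itself.

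Recipient libraries 1 to 4 held 8.92, 48.8, 51.3 and 11.5% B-cell-like cells, and 7.61, 3.04, 8.02 and 2.85% plasmacytoid-dendritic-cell-like cells. Classical-monocyte-like cells made up 32.5, 16.9, 21.7 and 32.7%, and unnamed cells 27.2, 18.0, 3.43 and 36.2%. Peripheral cluster 10, 1038 cells with a median of 910 UMIs and 65.3% from library 8, was led by Prg4, Alox15, Saa3 and Cxcl13 and had 8 of 10 macrophage markers raised. Peripheral library 6 had 13 genes at least 2-fold above every other library in classical-monocyte-like cells, among them Dhrs3 (138 CPM, median of the others 20.3) and Fam20c (60.7 and 12.7).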
